A study of Mus musculus with 20 samples.

How the data were processed

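The series measured RNA in mouse embryonic stem cells (mESCs), by the labels a male 129P2/OlaHsd line, which can form every tissue of the embryo. Its 20 labelled samples fall into 3 droplet single-cell experiments, each with a transcriptome library and a matching barcodelet library, and 14 bulk libraries. A barcodelet is a short synthetic RNA that is transfected into the cells of a well so that each cell carries a tag of its treatment into a pooled single-cell library. The bulk libraries were made with QuantSeq, a kit that reads the 3′ ends of polyadenylated RNA.

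The submitters' processing notes name Cell Ranger 1.3.1, STAR 2.5.2b and HTSeq 0.9.1 and the mouse build mm10, with no role or order. Which tool aligned and counted which library, and whether counting used the strand, is not given in the sources used here. The deposited single-cell matrices hold raw UMI counts (molecules per gene and cell) of called cells, and the deposited bulk table holds raw read counts per Ensembl gene; neither was normalised. Per the labels' protocols, the barcodelet libraries were the short-fragment part of the same cDNA. The authors also deposited the barcodelet counts of each cell, the fraction of those counts taken by its most abundant barcodelets, the population it was assigned to, and design tables that tie barcodelets to treatments. The deposited assignments were used as they stand; how cells were assigned is not given in the sources used here. The deposited bulk table has 54146 gene rows, of which 54079 carry a symbol in GENCODE vM21 (GRCm38), the annotation used for coordinates. It has 13 library columns: the replicate numbered 2 of the sorted Foxa2GFPplus group was not analysed here. Coordinates are 1-based. Genes that overlap another annotated gene have uncertain counts where strand or overlap rules are unknown. Among those named below these include Tcfl5 (Col9a3), Hoxb5 (Hoxb5os), Otx2 (Otx2os1), Slx1b (Bola2) and Hoxc8 (Hoxc5). Sprr2a3 belongs to a family of near-identical copies, and its counts are uncertain for the same reason.

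Single cells are not replicates, so the UMI counts of the cells assigned to each population were summed. No doublet caller was run and no doublet was removed beyond the deposited assignments, so cells that carry a pair of tags were left out only where those assignments leave them out. Populations with at least 5 cells entered the tests. A population was a treatment condition in the germ layer experiment, where each of 32 conditions had 1 population and the spread came from the residuals of an additive model, and a well in the mesendoderm and mixed experiments. Each gene was fitted with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood test, Benjamini-Hochberg adjustment, 2-sided, adjusted p under 0.05) in R 4.3.3. Pathway levels were coded 0.5 for plus and -0.5 for minus, so that a pathway effect is the log2 change from minus to plus averaged over the levels of the others. Control wells of the mixed experiment were coded 0 with an indicator of their own. Interactions were fitted as products. An interaction is the effect of a pathway where the second is plus, less its effect where the second is minus. P-values were adjusted over the genes of each pair on its own. Counts summed over pairs are thus not controlled over the pairs together. The bulk libraries were fitted as a transfection set and a sorting set. Below, log2 changes carry their standard errors, levels are CPM (counts scaled to a common library total) as mean ± SD over populations or libraries, and every adjusted p of a gene is from edgeR.

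Before the data were examined, 29 lists of 356 genes (targets of signalling pathways, markers of lineages, stress and metabolic responses) were fixed from textbook knowledge, together with the groups, the tests, the naming rule and most alternatives. Lists with at least 4 tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with an estimated correlation; list p-values were adjusted over the lists of a comparison. Counts of list members that rose or fell are given over all genes tested and adjusted over the list alone. Some genes belong to several lists, so results of different lists are not independent. A list score was the mean over members of log2(CPM + 5), compared between pathway levels by a permutation test of 100000 resamples. Named genes were those with the largest fitted changes each way among genes with an adjusted p under 0.05 and a mean CPM of at least 10 (10 each way in bulk, 5 each way in single-cell comparisons), leaving unnamed gene models, mitochondrial and ribosomal protein genes out of the naming but in the counts. To these were added, for each list described, its 2 to 4 members with the smallest adjusted p and the member of opposite direction with the smallest, and Foxa2 and Tdgf1 in bulk.

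The procedure was tested on simulated counts drawn from the real means and library sizes with 200 genes changed. At a 2-fold change, 98.5% of the changed genes were recovered for the Wnt effect in the germ layer experiment (10614 genes), 100% in the mesendoderm experiment (2328 genes) and 95.5% in the undirected wells of the mixed experiment (8791 genes). Bulk recovered far less: 25.4% at 2-fold and 75.8% at 4-fold for 24 h after transfection against untransfected cells (11631 genes), and 1.49% and 25.8% for Foxa2GFPplus against Foxa2GFPminus (13654 genes). Of the genes left unchanged, 0.0318% to 0.823% were called.

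The alternatives were median-of-ratios scaling, no filter on low counts, DESeq2 1.42.0, all bulk libraries in 1 fit, the replicate number as a block, a minimum of 20 cells, leaving out the 5% of cells with the most UMIs, a model with all pairwise products, each replicate left out in turn, an estimated inter-gene correlation, and pseudocounts of 1 and 20. Added after seeing the data were a crossed numbering of the untransfected libraries, mesendoderm counts summed per condition, and Foxa2GFPplus replicate 1 as the sole library of its group. Tables were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9. The p-values measure only the spread between these samples, which the labels assign to 1 cell line. Intervals on shares are exact Clopper-Pearson intervals at 95% and cover counting error alone.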

Results

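Mouse embryonic stem cells were profiled in 3 pooled single-cell experiments and in 13 bulk libraries. In the germ layer experiment, cells were treated for 24 h with all 32 combinations of 5 signals, each given as an activator (plus) or an inhibitor (minus). RA stands for retinoic acid against an antagonist of RA receptors, and Wnt for a GSK3 inhibitor, which activates Wnt signalling, against IWR1. Tgfb stands for Activin A against A8301, Bmp for Bmp4 against Dorsomorphin, and Fgf for Fgf2 against UO126, a MEK inhibitor. In the mesendoderm experiment, cells were first held for 24 h with Wnt, Tgfb and Fgf activated and RA and Bmp inhibited. They then received all combinations of 7 signals, which added Notch and Sonic hedgehog (Shh), in 384 wells. In the mixed experiment, 144 wells combined the 5 signals with an undirected or a mesendoderm start, 8 control wells per start included. The compounds behind plus and minus in the last 2 designs are not named in the tables used here. The bulk libraries covered untransfected cells, cells 24 h and 72 h after barcodelet transfection (2 libraries each), and sorted cells labelled Foxa2GFPplus (3), Foxa2GFPminus (2) and Tdgf1GFPplus (2).

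Over all cells the median was 14214 UMIs in the germ layer, 10583 in the mesendoderm and 19101 in the mixed experiment, with 3808, 2985 and 4181 genes. Cells assigned to a population had a median of 15314, 11700.0 and 19105 UMIs. Of 8421 germ layer cells, 4350 were assigned (51.7%, 95% interval 50.6% to 52.7%), with 70 to 230 cells per condition and 991630 to 3816595 UMIs. Of 12781 mesendoderm cells, 2899 were assigned (22.7%, 22.0% to 23.4%), with a median of 7 cells over all 384 wells, and 300 wells held at least 5 cells, with 27701 to 332644 UMIs. Of 5944 mixed cells, 4869 were assigned (81.9%, 80.9% to 82.9%), with a median of 31 cells over all 144 wells, and 142 wells entered the tests, with 101140 to 2119355 UMIs. Bulk libraries held 4960272 and 5134534 reads in genes (untransfected), 4257218 and 2899646 (24 h), 4788626 and 4106580 (72 h), 2906282 and 3469775 (Foxa2GFPminus), 5988930, 14874469 and 12839568 (Foxa2GFPplus 1, 3 and 4), and 4660092 and 5211600 (Tdgf1GFPplus).

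Few genes were called after barcodelet transfection in bulk, where most 2-fold changes would be missed (25.4% recovered in the simulation at 24 h). At 24 h Tcfl5, a basic helix-loop-helix factor (ENSMUSG00000038932.13, chr2:180621956-180642708), rose by a log2 of 3.25 ± 0.28, to 108 ± 34.3 from 11.2 ± 1.39 CPM (n = 2 each, adjusted p = 3e-06). At 72 h it stood 2.26 ± 0.28 above untransfected cells (53.6 ± 12.9 CPM, adjusted p = 0.000664). Gm45554, a long noncoding RNA (ENSMUSG00000110362.1, chr8:53436100-53480650), and Cntnap5a (chr1:115684756-116587323) rose at both times from untransfected levels near 0; both were picked after their values were seen. Dusp6, an ERK phosphatase induced by FGF signalling (ENSMUSG00000019960.8, chr10:99263231-99267489), fell by 1.57 ± 0.27 at 24 h (13.4 ± 3.88 against 40.7 ± 7.31 CPM, adjusted p = 0.0327).

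Of 11631 tested genes, 3 rose and 1 fell at 24 h, and 3 rose and 0 fell at 72 h, where 626 had an unadjusted edgeR p under 0.05. Of 14 FGF and ERK target genes, 1 fell at 24 h (6 adjusted over the list alone, median -0.55, camera adjusted p = 0.000178), and Spry2, a feedback inhibitor of the pathway, stood at -1.35 ± 0.31 (adjusted p = 0.55). That list's adjusted p = 0.543 with an estimated correlation. Of 5 caudal epiblast genes, 0 passed over all genes at 72 h and 3 fell adjusted over the list alone (camera adjusted p = 0.00165, and adjusted p = 0.589 with an estimated correlation), with Cdx2 at -1.38 ± 0.42 (adjusted p = 0.84). Between 72 h and 24 h, edgeR and DESeq2 both called 0 genes, with 369 at an unadjusted edgeR p under 0.05; Dusp6 stood 1.39 ± 0.27 higher at 72 h (adjusted p = 0.67). The Dusp6 call at 24 h ended without 24 h replicate 2 (adjusted p = 0.645), without untransfected replicate 1 (0.784) and in the fit of all 13 libraries. Without the filter on low counts the counts were 14 at 24 h, 21 at 72 h and 13 between the times. Without 72 h replicate 1 the count was 43 at 72 h and 16 between the times, where it was 6 without 24 h replicate 1 and 1 without 24 h replicate 2. The fit of all 13 libraries gave 2 at 24 h and 0 at 72 h (187 at an unadjusted edgeR p under 0.05).

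**Figure D1:**
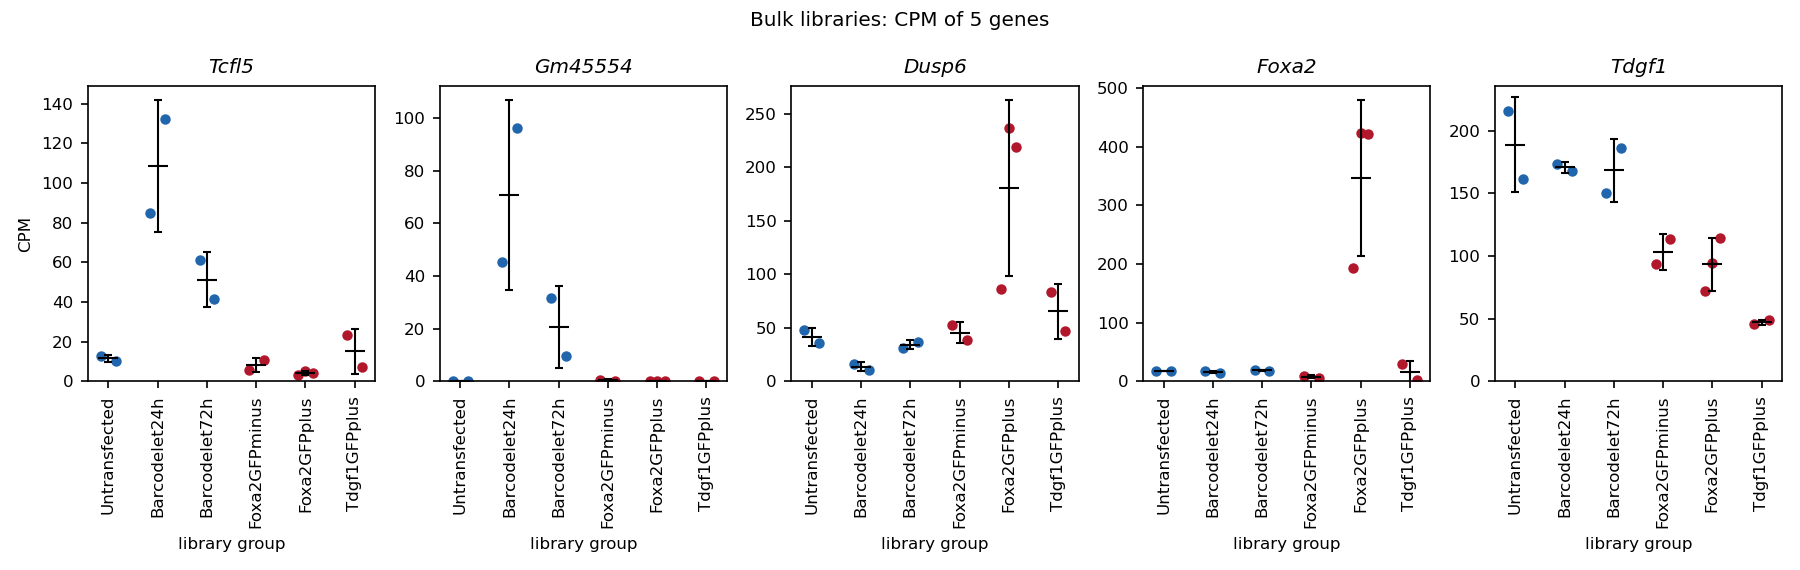
CPM (vertical axes) of Tcfl5, Gm45554, Dusp6, Foxa2 and Tdgf1 in the 13 bulk libraries by label (horizontal axes). Each point is 1 library (blue, transfection set; red, sorted set) and bars give the mean ± SD.

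The sorted libraries differed in Foxa2, a forkhead factor of endoderm and axial mesoderm (ENSMUSG00000037025.11, chr2:148042877-148046969). Scaled by read total alone, it stood at 192.9, 424 and 422 CPM in the 3 Foxa2GFPplus libraries, 9.63 and 6.05 in Foxa2GFPminus, 29.0 and 2.88 in the libraries labelled Tdgf1GFPplus, and 17.1 and 16.9 in untransfected cells. Tdgf1, a Nodal co-receptor, stood at 45.9 and 48.7 CPM in the libraries labelled Tdgf1GFPplus, 93.2 and 113.6 in Foxa2GFPminus, and 216 and 162 in untransfected cells. The sorted libraries also differed from the others in composition. Gm42418, a gene that overlaps ribosomal RNA sequence, took 29.7% and 41.0% of Foxa2GFPminus reads, 26.9%, 15.7% and 18.5% of Foxa2GFPplus reads and 24.6% and 42.6% of Tdgf1GFPplus reads. In unsorted libraries it took 2.63% to 10.6%. Ribosomal protein genes took 4.70% to 10.2% of reads in sorted and 20.8% to 27.9% in unsorted libraries.

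Against Foxa2GFPminus, the Foxa2GFPplus libraries had more Cdx2, a caudal homeobox factor (207 ± 145 against 3.61 ± 3.56 CPM, adjusted p = 0.0106), and Sox17, an endoderm factor (21.3 ± 7.28 against 0.574 ± 0.812 CPM, adjusted p = 0.0124). Nog, a secreted BMP antagonist, was also higher (26.9 ± 15.1 against 1.48 ± 0.473 CPM, adjusted p = 0.012), and Foxa2 rose by 4.88 ± 0.72 (adjusted p = 0.00577). Nr5a2, a nuclear receptor of the naive pluripotency network, fell by 4.90 ± 0.37 (1.43 ± 0.219 against 42.0 ± 10.1 CPM, adjusted p = 0.000198). Mylpf, a muscle myosin light chain gene, fell by 4.85 ± 0.44 (adjusted p = 0.000484) and the small nucleolar RNA Snord89 (chr1:39548745-39548854) by 4.60 ± 0.50 (adjusted p = 0.00111). Of 14 naive pluripotency genes 10 fell (12 adjusted over the list alone, median -3.07), among them Tdh by 4.05 ± 0.30, Esrrb by 3.70 ± 0.40 and Zfp42 by 3.67 ± 0.40 (camera adjusted p = 3.2e-11, and adjusted p = 0.221 with an estimated correlation). Of 12 genes of the anterior axial mesendoderm, 6 rose (8 adjusted over the list alone), among them Lhx1 by 1.87 ± 0.36 (camera adjusted p = 1.73e-06, and adjusted p = 0.3 with an estimated correlation). Of 14 primitive streak genes, 2 rose, with Fgf8 up by 2.85 ± 0.55 (8 up and 1 down adjusted over the list alone, camera adjusted p = 0.00052, and adjusted p = 0.3 with an estimated correlation).

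In that comparison (n = 3 and 2) edgeR called 120 genes higher and 207 lower of 13654, and DESeq2 called 991 in all. Leaving out a library moved the total between 44, without Foxa2GFPminus replicate 2, and 2909, without Foxa2GFPplus replicate 1. Without either Foxa2GFPminus library the Foxa2 call itself ended. Of 27 values of named genes in comparisons with Foxa2GFPminus, 6 lost their call without replicate 1 and 12 without replicate 2, Foxa2 among them. Foxa2GFPplus 1 correlated with 3 and 4 at 0.870 and 0.834 in log2 CPM, and 3 with 4 at 0.973. The 3 Y-linked genes Ddx3y, Uty and Eif2s3y summed to 0, 71 and 65 counts in Foxa2GFPplus 1, 3 and 4, 0 in both Foxa2GFPminus libraries and 250.0 and 208 in the libraries labelled Tdgf1GFPplus. Scaled by read total, the sums were 4.77 and 5.06 CPM in Foxa2GFPplus 3 and 4, and 53.6 and 39.9 CPM in the libraries labelled Tdgf1GFPplus.

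Against the libraries labelled Tdgf1GFPplus, Foxa2GFPplus libraries had more Hoxb1, a hindbrain and RA-induced Hox gene (up by 5.21 ± 0.59, to 109 ± 39.0 from 2.88 ± 1.55 CPM, adjusted p = 0.000615). Cdx2 rose by 5.62 ± 0.92 (adjusted p = 0.00511) and Foxa2 by 3.99 ± 0.67 (adjusted p = 0.0059). Calcoco2 fell by 6.36 ± 0.49 and Mylpf by 5.91 ± 0.46 (both adjusted p = 9.28e-05). Naive pluripotency genes fell (12 of 14, 13 adjusted over the list alone, with Zfp42 down by 4.91 ± 0.41, camera adjusted p = 1.7e-12, and adjusted p = 0.137 with an estimated correlation). Hedgehog targets rose (3 of 5, and 5 adjusted over the list alone), with Ptch1, the Hedgehog receptor, up by 4.62 ± 0.48 and Gli1 by 4.18 ± 0.57 (camera adjusted p = 0.000418, and adjusted p = 0.137 with an estimated correlation). So did paraxial mesoderm genes (6 of 12, and 6 adjusted over the list alone), with the Wnt agonist Rspo3 up by 3.796 ± 0.35 (camera adjusted p = 0.000369, and adjusted p = 0.279 with an estimated correlation). Of 13654 genes 656 were higher and 741 lower. The total fell to 230.0 without Tdgf1GFPplus replicate 2 and rose to 4134 without Foxa2GFPplus replicate 1.

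Between the libraries labelled Tdgf1GFPplus and Foxa2GFPminus (n = 2 each), edgeR called 0 genes, with 1321 at an unadjusted p under 0.05, and DESeq2 called 138. In the fit of all 13 libraries edgeR called 79, and without the filter on low counts 173. Of 12 paraxial mesoderm genes 0 passed over all genes and 6 fell adjusted over the list alone, with Rspo3 at -2.08 ± 0.34 (adjusted p = 0.15, camera adjusted p = 2.76e-05, and adjusted p = 0.303 with an estimated correlation). Of 14 glycolysis and hypoxia genes 0 passed over all genes and 7 fell adjusted over the list alone, with Bnip3, a hypoxia-induced mitophagy receptor, at -2.63 ± 0.46 (adjusted p = 0.16, camera adjusted p = 0.000191, and adjusted p = 0.311 with an estimated correlation).

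In the germ layer experiment (16 populations at each level), RA raised Stra8, a gene needed for entry into meiosis (ENSMUSG00000029848.11, chr6:34920163-34939344), by 4.13 ± 0.20, to 41.3 ± 17.4 from 2.13 ± 1.36 CPM (adjusted p = 9.76e-18). The RA receptor gene Rarb rose by 3.08 ± 0.17 (adjusted p = 5.44e-16). Otx2, a factor of the epiblast and anterior brain (chr14:48657677-48673819), fell by 2.37 ± 0.22, to 7.36 ± 3.92 from 39.1 ± 25.7 CPM (adjusted p = 2.27e-10). Eomes, a T-box factor of the primitive streak, fell by 2.54 ± 0.23 (adjusted p = 2.27e-10). Of 15 RA target genes 14 rose (15 adjusted over the list alone, median 1.97), among them Crabp2 by 2.60 ± 0.14 and Meis1 by 2.54 ± 0.17 (camera adjusted p = 3.54e-22, and adjusted p = 8.97e-07 with an estimated correlation). Of 10 general pluripotency genes 8 fell (8 down and 1 up adjusted over the list alone), with Pou5f1 down by 1.49 ± 0.07 (camera adjusted p = 5.16e-06, and adjusted p = 0.0135 with an estimated correlation). Of 10 primitive streak genes 7 fell and 1 rose (8 and 2 adjusted over the list alone), with T down by 1.89 ± 0.31 (camera adjusted p = 0.00462, and adjusted p = 0.354 with an estimated correlation). Of 10614 genes 1492 rose and 1445 fell.

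With Wnt activation in the germ layer experiment, Hoxc8 rose by 2.84 ± 0.29, to 29.8 ± 30.2 from 4.42 ± 3.81 CPM (adjusted p = 2.48e-09). Ahdc1 (chr4:133011260-133078110) fell by 2.57 ± 0.06, to 27.1 ± 5.29 from 159 ± 17.3 CPM (adjusted p = 1.32e-26). Pou3f1, a POU factor of the epiblast and neural tissue, fell by 2.17 ± 0.20 (adjusted p = 4.25e-10). Of 14 Wnt target genes 11 rose (11 adjusted over the list alone), with Axin2, a feedback inhibitor of the pathway (chr11:108920349-108950783), up by 1.51 ± 0.09 and Nkd1 by 1.99 ± 0.15 (camera adjusted p = 4.3e-14, and adjusted p = 0.000107 with an estimated correlation). Of 14 caudal epiblast genes 11 rose and 1 fell (12 and 1 adjusted over the list alone), with Cdx1 up by 2.42 ± 0.16 and Cdx2 by 2.41 ± 0.23 (camera adjusted p = 3.56e-09, and adjusted p = 0.0429 with an estimated correlation). Of 9 primed epiblast genes 5 fell (6 adjusted over the list alone, camera adjusted p = 8.38e-05, and adjusted p = 0.0431 with an estimated correlation). Of 12 neural ectoderm genes 6 fell (9 down and 1 up adjusted over the list alone), with Zic2 down by 1.00 ± 0.19 (camera adjusted p = 0.0034, and adjusted p = 0.206 with an estimated correlation). In all, 1280 genes rose and 1262 fell.

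Activin A against A8301 raised the Nodal antagonist Lefty2 (chr1:180893108-180899103) by 2.80 ± 0.23, to 112 ± 111 from 13.6 ± 6.85 CPM (adjusted p = 1.27e-10). Lefty1 (chr1:180935022-180938400) rose by 2.15 ± 0.41 (adjusted p = 0.000439). Hand1, a factor of lateral and extraembryonic mesoderm (chr11:57828705-57832818), fell by 1.52 ± 0.20, to 22.2 ± 19.6 from 74.6 ± 86.3 CPM (adjusted p = 1.2e-06). Of 12 Nodal and Activin target genes 10 rose (10 adjusted over the list alone), with Nodal up by 2.01 ± 0.11 (camera adjusted p = 1.88e-22, and adjusted p = 4.55e-08 with an estimated correlation). Of 10 primitive streak genes 7 rose (8 adjusted over the list alone), with Eomes up by 2.07 ± 0.24 (camera adjusted p = 4.7e-10, and adjusted p = 0.0045 with an estimated correlation). The Nodal and streak lists share members, Eomes and Nodal among them. Of 14 BMP target genes 6 fell and 1 rose (9 and 1 adjusted over the list alone), with Id3 down by 0.52 ± 0.09 and Smad7 up by 0.59 ± 0.08 (camera adjusted p = 0.00119, and adjusted p = 0.0861 with an estimated correlation). In all, 432 genes rose and 313 fell, and with pairwise products in the model the total was 1132.

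Bmp4 against Dorsomorphin moved the most genes of the 5 germ layer contrasts, 2294 up and 2281 down. Hand1 rose by 3.62 ± 0.22, to 89.8 ± 75.0 from 6.96 ± 3.84 CPM (adjusted p = 6.41e-15). Tbx3 rose by 2.99 ± 0.12 (adjusted p = 1.51e-19) and Tfap2a, a surface ectoderm factor, by 3.10 ± 0.17 (adjusted p = 7.76e-16). Foxb1, a factor of the neural tube, fell by 2.65 ± 0.31 (2.57 ± 1.03 against 18.5 ± 15.4 CPM, adjusted p = 1.57e-08) and Lefty1 by 2.12 ± 0.40 (adjusted p = 6.34e-05). All 14 BMP target genes rose (median 2.43), with Msx2 (chr13:53466884-53473074) up by 2.58 ± 0.12 (camera adjusted p = 6.89e-20, and adjusted p = 5.94e-06 with an estimated correlation). All 10 lateral mesoderm genes rose (camera adjusted p = 2.49e-09, and adjusted p = 0.00119 with an estimated correlation). So did all 10 surface ectoderm genes, with Gata3 up by 2.24 ± 0.11 and Krt18 by 1.69 ± 0.11 (camera adjusted p = 5.4e-11, and adjusted p = 0.00124 with an estimated correlation). These 3 counts were unchanged adjusted over the list alone. The lists share members, so they are not independent results. Hand1, Msx1 and Msx2 are on the lists of BMP targets and lateral mesoderm. Gata3, Tfap2a and Dlx5 are on those of BMP targets and surface ectoderm. Of 12 neural ectoderm genes 10 fell (10 adjusted over the list alone), with Sox1 down by 2.73 ± 0.33 and Pax6 by 2.38 ± 0.37 (camera adjusted p = 0.00164, and adjusted p = 0.131 with an estimated correlation).

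Fgf2 against UO126 raised Dusp4 (chr8:34807297-34819894) by 1.90 ± 0.21, to 36.4 ± 20.02 from 9.48 ± 4.65 CPM (adjusted p = 1.7e-07). Etv4 (chr11:101769742-101785371), an ETS factor induced by ERK, rose by 1.62 ± 0.16 (adjusted p = 1.46e-08). Fgfr2, an FGF receptor gene, fell by 0.91 ± 0.13 (10.1 ± 7.83 against 18.1 ± 10.1 CPM, adjusted p = 2.29e-05). Of 15 FGF and ERK target genes 11 rose (12 adjusted over the list alone, median 0.77), with Dusp6 up by 1.45 ± 0.16 and Spry4 (chr18:38586247-38601415) by 2.10 ± 0.24 (camera adjusted p = 5.48e-21, and adjusted p = 0.00053 with an estimated correlation). Of 10 general pluripotency genes 5 rose (6 adjusted over the list alone), with Utf1 up by 1.09 ± 0.16 (camera adjusted p = 1.46e-06, and adjusted p = 0.00868 with an estimated correlation). In all, 486 genes rose and 356 fell, and with pairwise products in the model the total was 1331.

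**Figure D2:**
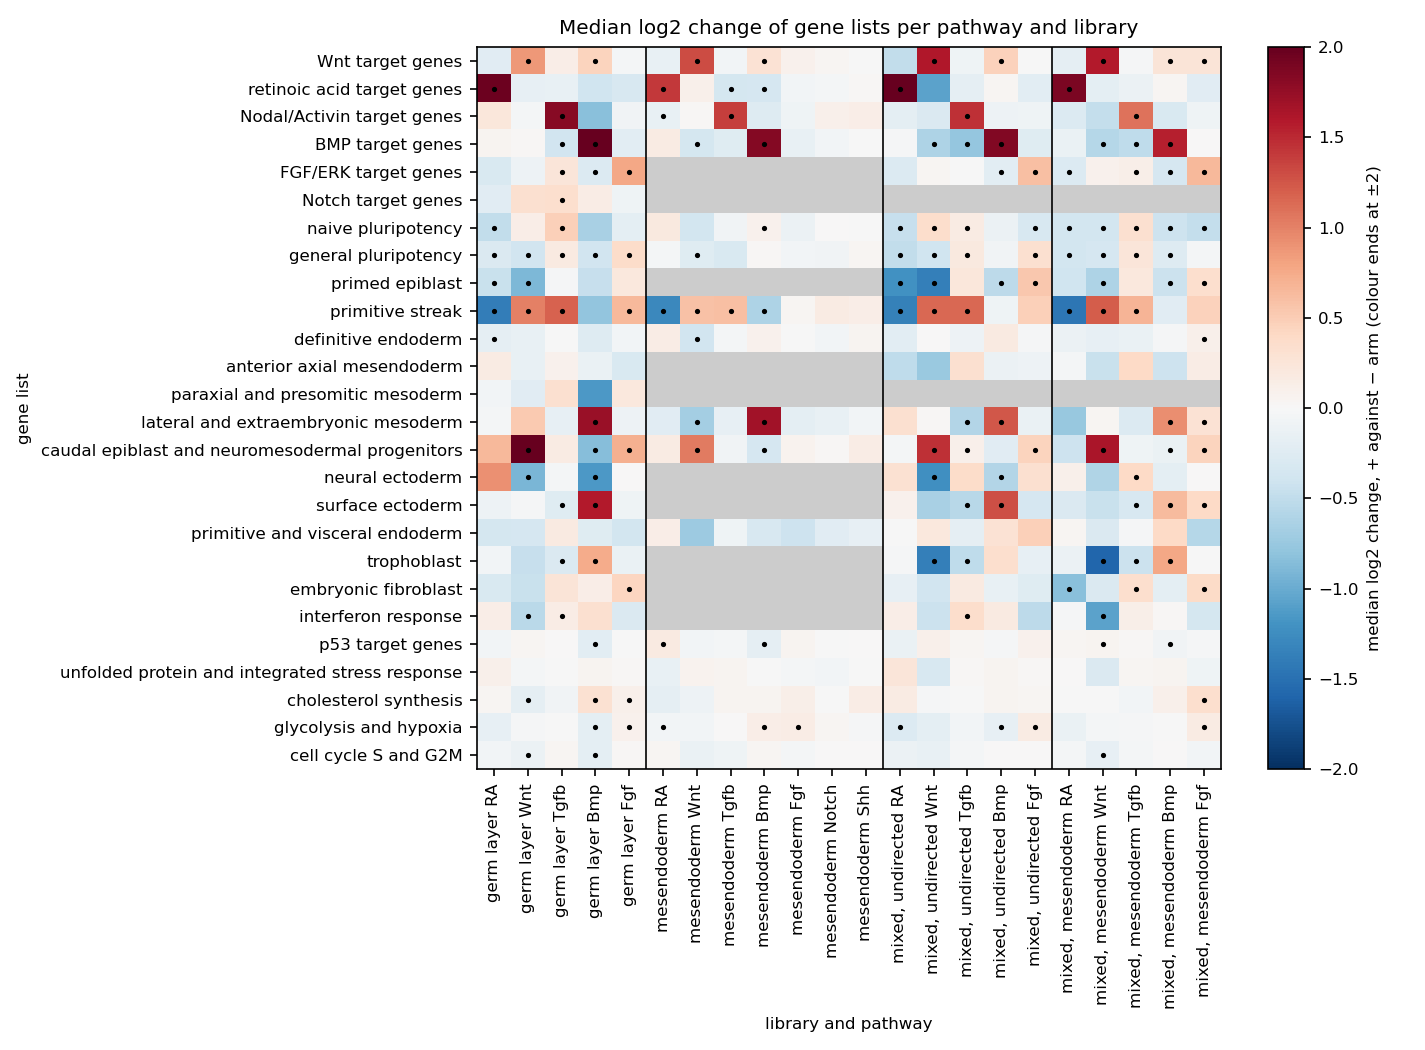
Median log2 change from minus to plus (colour) over the tested members of each gene list (vertical axis) per experiment and pathway (horizontal axis). Dots mark lists called by camera at the preset correlation, grey marks lists with too few tested members, and no error is drawn.

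Pathway effects depended on one another. Over all 10 pairs in the germ layer experiment, 863 interaction calls were positive and 758 negative, a gene counting once for each pair, with 11410 genes tested per pair. Wnt with Bmp had 442, RA with Wnt 414, and RA with Bmp and Tgfb with Bmp 344 each. Wnt with Tgfb and Wnt with Fgf had 0 by edgeR (861 and 752 at an unadjusted p under 0.05). T, the mesoderm factor Brachyury, stood at 207 ± 187 CPM with Wnt plus and Bmp minus, and 76.5 ± 103 with both plus (n = 8 each). It stood at 49.1 ± 54.2 with Bmp plus alone and 21.7 ± 10.0 with both minus (interaction -2.64 ± 0.42, adjusted p = 0.00018). Lefty1 stood at 726 ± 684 CPM with Tgfb plus and Bmp minus against 40.6 ± 14.1 to 56.6 ± 17.8 in the other 3 combinations (-2.67 ± 0.29, adjusted p = 9.82e-07). Hand1 stood at 142 ± 74.8 CPM with Tgfb minus and Bmp plus and at 37.9 ± 15.9 with both plus (-1.71 ± 0.33, adjusted p = 0.00203). Hoxb1 stood at 3.55 ± 2.03 CPM with RA and Wnt both minus and at 22.7 ± 6.24, 38.3 ± 35.2 and 36.6 ± 22.4 with RA, Wnt or both plus (-2.39 ± 0.34, adjusted p = 4.7e-05). Slc2a1, a glucose transporter, stood at 419 ± 122 CPM with RA plus and Bmp minus and 191 ± 80.2 with both plus (-1.94 ± 0.12, adjusted p = 2.3e-13).

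List scores, mean RNA levels of markers and not amounts of a lineage, ranked the germ layer conditions. Each condition had 1 population, so each germ layer maximum rests on that population alone. The primitive streak score was highest, at 6.39, with Wnt, Tgfb and Fgf plus and RA and Bmp minus, and lowest, at 3.46, with RA as the sole plus (residual SD 0.394). The neural ectoderm score was highest, at 4.84, with RA as the sole plus (lowest 3.20, residual SD 0.248). The caudal epiblast score was highest, at 6.38, with RA, Wnt and Fgf plus (lowest 3.599, residual SD 0.370). The lateral mesoderm score was highest, at 5.63, with RA and Bmp plus (lowest 3.797, residual SD 0.177), and the surface ectoderm score, at 6.54, with RA, Wnt and Bmp plus (lowest 4.53, residual SD 0.202). Of 130 pairs of list and pathway, 28 passed the permutation test in the germ layer experiment.

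**Figure D3:**
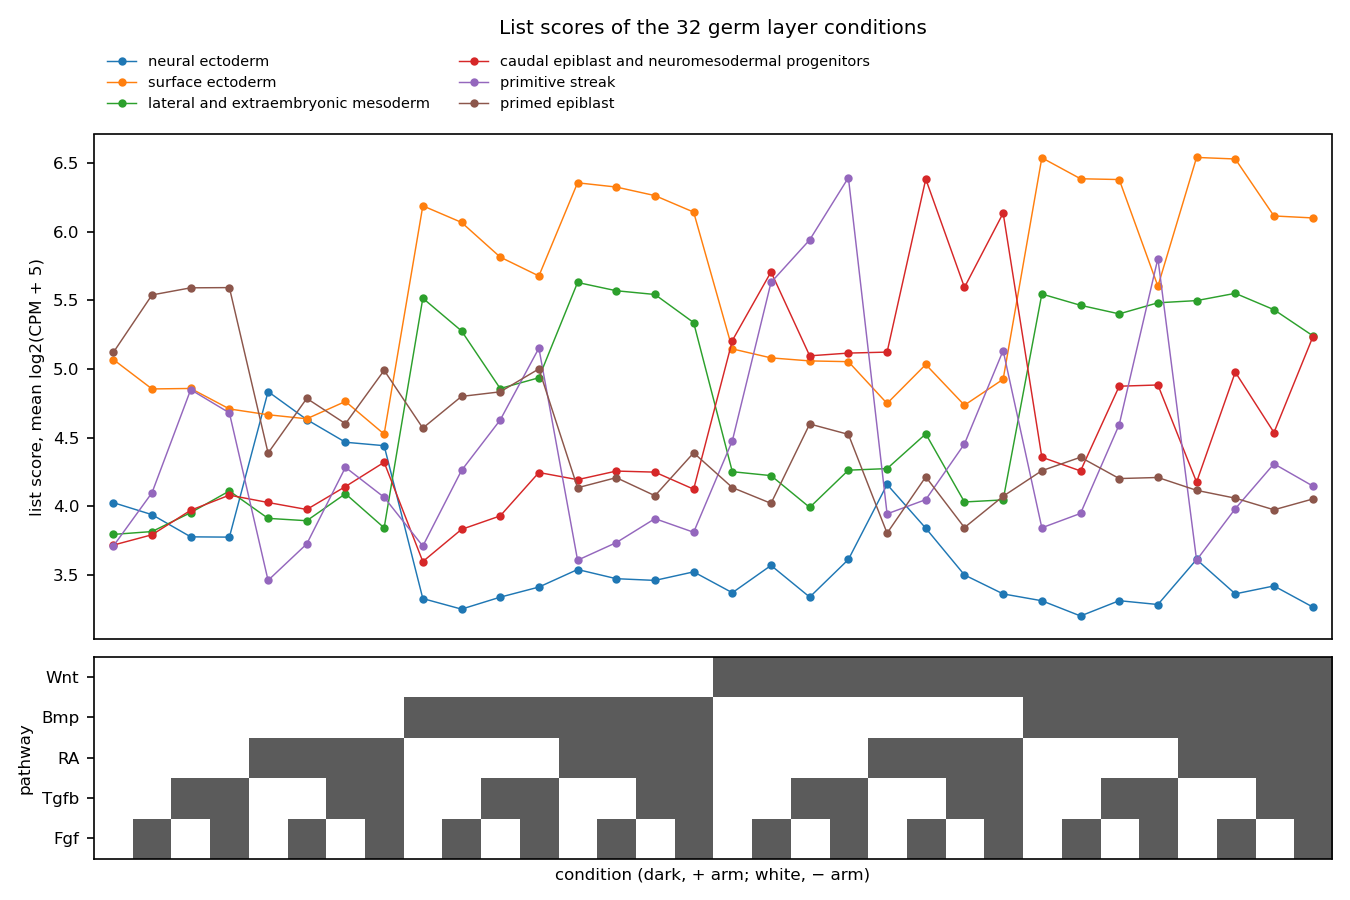
Scores of 6 lineage lists (vertical axis, mean log2(CPM + 5) of the members) in the 32 germ layer conditions (horizontal axis, 1 population each, so no error is drawn). The lower panel gives each condition's pathway levels, dark for plus and white for minus.

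In the mesendoderm experiment, RA again raised Stra8, by 3.03 ± 0.19 (97.4 ± 126 against 8.95 ± 25.5 CPM, 146 and 154 wells, adjusted p = 7.54e-40). It lowered Mixl1, a homeobox gene of the primitive streak, by 1.60 ± 0.12 (63.3 ± 69.1 against 188 ± 160.2 CPM, adjusted p = 1.46e-31). All 8 RA targets rose (8 adjusted over the list alone, camera adjusted p = 2.12e-36, and adjusted p = 4.26e-22 with an estimated correlation). All 4 streak genes fell (4 adjusted over the list alone, camera adjusted p = 1.82e-12, and adjusted p = 1.9e-07 with an estimated correlation). Wnt raised Tlx2 by 2.54 ± 0.13 (184 ± 133 against 27.8 ± 40.9 CPM, 148 and 152 wells, adjusted p = 3.17e-54) and Nkd1 by 2.40 ± 0.08. It lowered Hand1 by 1.69 ± 0.17 (adjusted p = 1.29e-19) and the keratin Krt8 by 1.46 ± 0.10 (adjusted p = 2.74e-32). All 10 Wnt targets rose (10 adjusted over the list alone, camera adjusted p = 3.43e-31, and adjusted p = 8.88e-13 with an estimated correlation). Of 6 definitive endoderm genes 4 fell and 1 rose (5 and 1 adjusted over the list alone, camera adjusted p = 0.00316, and adjusted p = 0.039 with an estimated correlation). RA moved 271 genes up and 239 down of 2328, and Wnt 464 and 457. Without the filter on low counts the totals were 1379 and 2630, and without replicate 0 the RA total was 333.

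Tgfb raised Lefty1 by 2.77 ± 0.15 (342 ± 461 against 38.9 ± 76.3 CPM, 108 and 192 wells) and Lefty2 by 2.63 ± 0.14 (both adjusted p = 2.44e-49). It lowered Hand1 by 1.13 ± 0.18 and Cdx2 by 0.86 ± 0.10. All 6 Nodal and Activin targets rose (6 adjusted over the list alone, camera adjusted p = 3.48e-38, and adjusted p = 5.72e-25 with an estimated correlation). Bmp raised Msx2 by 2.24 ± 0.10 (139 ± 59.8 against 26.9 ± 30.0 CPM, 157 and 143 wells, adjusted p = 4.97e-61) and Id1 (chr2:152736251-152737410) by 1.87 ± 0.08. It lowered Lefty1 by 1.94 ± 0.15 (adjusted p = 1.78e-27). All 8 BMP targets rose (8 adjusted over the list alone, camera adjusted p = 2.79e-54, and adjusted p = 3.09e-20 with an estimated correlation). Fgf raised S100a6, a calcium-binding protein gene, by 1.53 ± 0.11 (259 ± 178 against 88.0 ± 70.1 CPM, 168 and 132 wells, adjusted p = 1.86e-30) and lowered Stra8 by 1.17 ± 0.17 (adjusted p = 8.74e-09). Of 8 glycolysis genes 4 rose with Fgf (4 adjusted over the list alone), with Ldha up by 0.36 ± 0.04 (camera adjusted p = 4.99e-06, and adjusted p = 0.00441 with an estimated correlation). Tgfb moved 235 genes, 107 of them down, Bmp 313 up and 369 down, and Fgf 216, with 88 up. Without the filter on low counts the totals were 532, 1442 and 397, and without replicate 0 the Tgfb and Fgf totals were 115 and 88.

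Notch and Shh moved few genes. The lists of Notch and Hedgehog targets had fewer than 4 tested members in this experiment and were not tested. Whether these signals moved their target lists thus stays open. With Notch plus, Pdia6 fell by 0.35 ± 0.05 (196 ± 66.1 against 252 ± 85.2 CPM, 153 and 147 wells, adjusted p = 1.64e-07), Rpn1 by 0.34 ± 0.05 (adjusted p = 1.64e-07) and P4hb by 0.28 ± 0.05 (adjusted p = 1.64e-05). In all, 4 genes rose and 23 fell with Notch, and the total was 11 without the filter on low counts and 9 without 1 of the replicates. With Shh plus, 1 gene rose: Slx1b, a subunit of a structure-specific nuclease (chr7:126689468-126695784), by 0.61 ± 0.12 (381 ± 383 against 247 ± 209 CPM, 158 and 142 wells, adjusted p = 0.00156). The Shh call ended without replicate 1, where edgeR called 0. Slx1b also had an interaction of Tgfb with Notch (-1.81 ± 0.22, adjusted p = 2.32e-11), larger than its change with Shh. It stood at 636 ± 479.7 CPM with Tgfb plus and Notch minus (n = 55) and 199 ± 165 with both plus (n = 53). With Notch plus alone it stood at 261 ± 202 (n = 100) and with both minus at 213 ± 167 (n = 92).

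Interaction calls of the mesendoderm experiment, summed over 21 pairs, were positive for 242 and negative for 290, 320 of them for Wnt with Bmp. Hand1 stood at 136 ± 119 CPM with Bmp plus and Wnt minus (n = 77 wells) and at 24.5 ± 31.5 with both plus (n = 80, interaction -2.66 ± 0.38, adjusted p = 4.77e-09). Sp5, a Wnt target, stood at 35.96 ± 33.9 CPM with Bmp plus and Wnt minus and 142 ± 82.3 with both minus (n = 75). It stood at 254 ± 108 with Wnt plus alone (n = 68) and 191 ± 81.7 with both plus (1.62 ± 0.17, adjusted p = 7e-16). Dkk1, a Wnt antagonist, stood at 174 ± 154 CPM with Wnt plus and RA minus (n = 77) and 44.2 ± 46.4 with both plus (n = 71, -1.79 ± 0.26, adjusted p = 3.91e-08).

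In the mixed experiment from the undirected start, RA raised Stra8 by 4.46 ± 0.22 (471 ± 345 against 23.6 ± 26.7 CPM, 30 and 32 wells, 27.1 ± 28.0 in 8 control wells, adjusted p = 2.91e-41). It lowered Otx2 by 2.83 ± 0.21 (8.66 ± 8.60 against 56.1 ± 57.8 CPM, adjusted p = 6.15e-25). All 15 RA targets rose (15 adjusted over the list alone, camera adjusted p = 1.43e-34, and adjusted p = 3.98e-09 with an estimated correlation). Wnt raised Cdx1 (chr18:61018862-61036199) by 2.75 ± 0.12 (268 ± 196 against 39.6 ± 26.6 CPM, adjusted p = 9.39e-46). It lowered Pou3f1 by 3.81 ± 0.25 (4.55 ± 4.95 against 77.9 ± 79.5 CPM, adjusted p = 4.49e-30). All 10 primed epiblast genes fell with Wnt (10 adjusted over the list alone, camera adjusted p = 7.89e-09, and adjusted p = 0.00246 with an estimated correlation). Of 14 naive pluripotency genes 9 rose and 1 fell with Wnt (9 and 1 adjusted over the list alone), with Tdh up by 1.45 ± 0.12 and Tfcp2l1 by 1.46 ± 0.13 (camera adjusted p = 0.000141, and adjusted p = 0.0813 with an estimated correlation). Tgfb raised Lefty1 by 3.08 ± 0.21 (adjusted p = 2.65e-26), Bmp raised Id1 by 2.22 ± 0.14 (adjusted p = 2.02e-31) and Fgf raised Etv4 by 2.05 ± 0.17 (adjusted p = 7.29e-20). Of 8791 genes, 1483 rose and 1536 fell with RA, 1468 and 1708 with Wnt, 215 and 149 with Tgfb, 380 and 307 with Bmp, and 602 and 564 with Fgf. With at least 20 cells per well the Wnt, Bmp and Fgf totals were 1756, 340.0 and 712. Without replicate 1 the RA, Wnt, Tgfb, Bmp and Fgf totals were 1338, 1748, 123, 166 and 346.

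From the mesendoderm start, RA raised Cyp26a1, which degrades RA, by 2.83 ± 0.14 (90.1 ± 28.5 against 11.8 ± 7.90 CPM, 32 wells each, adjusted p = 4.92e-42). It lowered Bmp4 by 1.85 ± 0.19 (adjusted p = 4.98e-16). Wnt raised Tlx2 by 3.75 ± 0.18 (124 ± 83.9 against 9.64 ± 7.07 CPM) and Lmo2 by 3.47 ± 0.17 (both adjusted p = 1.31e-42). It lowered Hand1 by 2.71 ± 0.32 (adjusted p = 2.9e-13). With Wnt, 12 of 14 caudal epiblast genes rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 5.19e-16, and adjusted p = 3.86e-05 with an estimated correlation). All 7 trophoblast genes fell with Wnt (7 adjusted over the list alone, camera adjusted p = 6.98e-06, and adjusted p = 0.00587 with an estimated correlation). Tgfb raised Lefty2 by 2.78 ± 0.16 (adjusted p = 2.2e-34) and Bmp raised Msx2 by 2.16 ± 0.11 (adjusted p = 1.54e-38). Fgf raised S100a6 to 281 ± 153 from 91.7 ± 47.2 CPM (adjusted p = 1.87e-20). With Fgf, 11 of 13 FGF and ERK targets rose (12 adjusted over the list alone, camera adjusted p = 6.59e-15, and adjusted p = 4.4e-06 with an estimated correlation). So did 11 of 16 cholesterol synthesis genes (13 adjusted over the list alone, camera adjusted p = 1.74e-08, and adjusted p = 0.00106 with an estimated correlation). The genes up and down were 1262 and 1372 for RA, 1746 and 1866 for Wnt, 400.0 and 212 for Tgfb, 471 and 471 for Bmp, and 626 and 566 for Fgf. Without replicate 1 the RA, Wnt, Tgfb, Bmp and Fgf totals were 988, 1803, 142, 171 and 450.0.

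Averaged over the treatments, wells from the mesendoderm start (72) had more Hoxc8 than undirected wells (70), by 2.16 ± 0.24 (16.2 ± 13.8 against 3.76 ± 5.82 CPM, adjusted p = 6.08e-14). They had less of the endocytic receptor Lrp2, by 1.07 ± 0.16 (adjusted p = 2.22e-08). Of 12 Wnt targets 11 rose (11 adjusted over the list alone, camera adjusted p = 5.88e-14, and adjusted p = 0.000209 with an estimated correlation), with Ccnd2 up by 1.16 ± 0.10. All 5 embryonic fibroblast genes rose (5 adjusted over the list alone), with Vim up by 0.88 ± 0.10 and Fn1 by 0.72 ± 0.08 (camera adjusted p = 2.79e-08, and adjusted p = 5.17e-05 with an estimated correlation). In all 1249 genes were higher and 1005 lower, and the total was 1278 with at least 20 cells per well and 1089 without replicate 1. Mesendoderm wells were deeper, with a median of 837115 UMIs against 494122.5.

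The effects of RA and Wnt on Hoxb5 and Hoxb8 differed between the starts. Hoxb5 (chr11:96303336-96306121) stood at 56.6 ± 37.8 CPM in undirected wells with RA plus and Wnt minus (n = 16), 5.41 ± 5.16 with both plus (n = 14), 1.49 ± 2.43 with Wnt plus alone and 2.495 with both minus. From the mesendoderm start it stood at 11.6 ± 4.70, 13.8, 12.6 ± 7.25 and 3.19 in the same order. The RA effect from the mesendoderm start less that from the undirected start was -3.21 ± 0.38 for Hoxb5 (adjusted p = 4.13e-11) and -4.40 ± 0.38 for Hoxb8 (adjusted p = 2.53e-18). The same difference for Wnt was 4.10 ± 0.37 for Hoxb5 (adjusted p = 2.44e-17) and 3.31 ± 0.33 for Hoxb8 (adjusted p = 5.54e-15). Hox levels in the low groups amount to a few UMIs per well. Otx2 stood at 104.5 ± 43.3 CPM in undirected wells with RA and Wnt minus and at 20.1 ± 12.4 in the matching mesendoderm wells, with a difference in the RA effect of 2.12 ± 0.32 (adjusted p = 3.44e-07). Of 14 naive pluripotency genes, the Wnt effect was lower from the mesendoderm start for 10 and higher for 1 (12 and 1 adjusted over the list alone), with Tdh at -1.38 ± 0.15 and Zfp42 at -0.99 ± 0.14 (camera adjusted p = 9.52e-18, and adjusted p = 2.48e-05 with an estimated correlation).

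For RA 215 genes had a higher and 284 a lower effect from the mesendoderm start, for Wnt 364 and 319, for Bmp 4 and 13, and for Fgf 82 and 47. For Tgfb edgeR called 0 (450 at an unadjusted p under 0.05) and DESeq2 0, while edgeR called 42 without the filter on low counts and 3 with at least 20 cells per well. Among the Bmp differences Rspo3 stood at -1.68 ± 0.40 (adjusted p = 0.0271). Among the Fgf differences the keratin Krt18 stood at 1.17 ± 0.25 (adjusted p = 0.00281) and L1td1, a gene of pluripotent cells, at -0.72 ± 0.13 (adjusted p = 0.000287). These counts were smaller in a single replicate: without replicate 1 or 2 they were 57 and 145 for RA, 72 and 240.0 for Wnt, 8 and 9 for Fgf, and 0 and 0 for Bmp. In the model with pairwise products the RA count was 213. Without the 5% of cells with the most UMIs the Bmp and Fgf counts were 8 and 45. With at least 20 cells per well the RA and Wnt counts were 761 and 322.

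**Figure D4:**
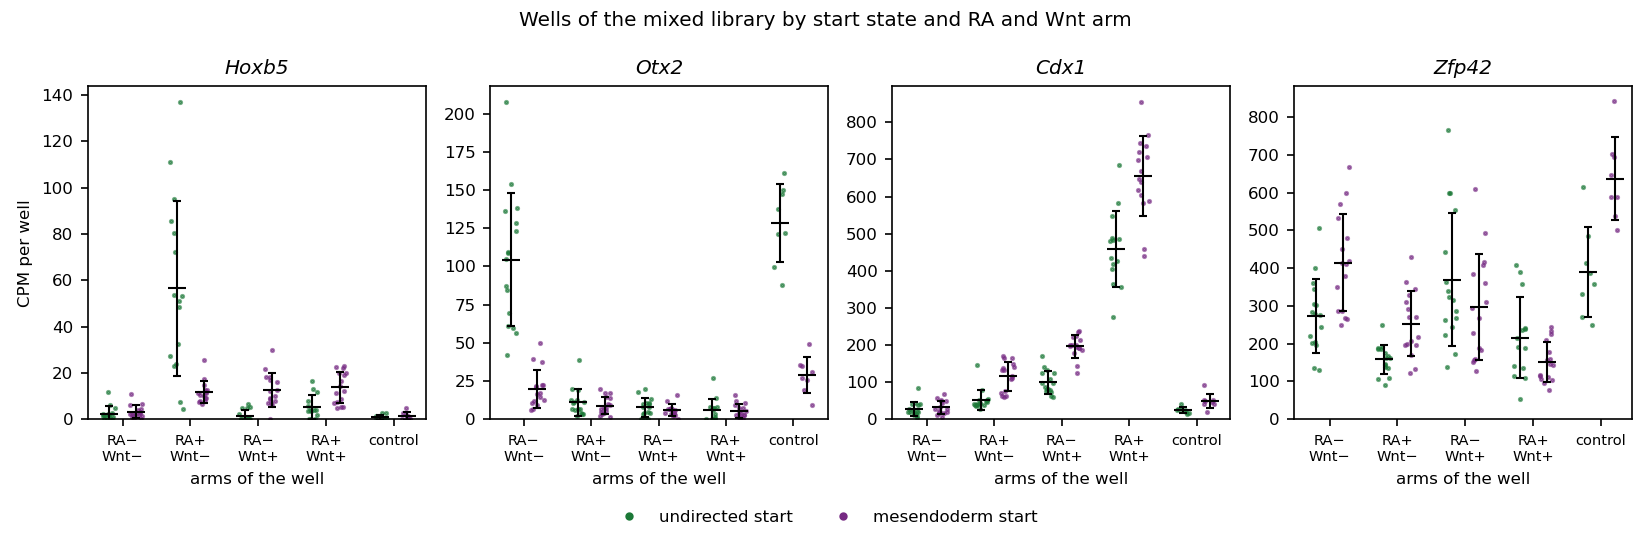
CPM of Hoxb5, Otx2, Cdx1 and Zfp42 (vertical axes) in mixed wells, by RA and Wnt level and in control wells (horizontal axes). Each point is 1 well (green, undirected start; purple, mesendoderm start) and bars give the mean ± SD.

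In the mixed experiment 533 interaction calls were positive and 418 negative, summed over pairs and starts, 318 of them for RA with Wnt from the undirected and 235 from the mesendoderm start, and 182 for Wnt with Bmp from the mesendoderm start. Otx2 from the undirected start stood at 104 ± 42.8 CPM with RA and Wnt minus and at 5.92 ± 7.36 to 10.9 ± 8.95 in the other 3 combinations (interaction 2.92 ± 0.68, adjusted p = 0.0039). Crabp2, an RA-binding protein gene, stood at 129.99 ± 89.0 CPM with RA plus and Wnt minus and 14.3 ± 13.4 with both plus (-2.89 ± 0.54, adjusted p = 0.000161). From the mesendoderm start Hand1 stood at 86.7 ± 86.6 CPM with Bmp plus and Wnt minus and 3.98 ± 5.08 with both plus (-3.49 ± 0.59, adjusted p = 1.55e-05). Mixl1 stood at 123 ± 89.4 CPM with Wnt and Fgf plus and 38.3 ± 31.5 with Wnt plus alone (2.19 ± 0.34, adjusted p = 8.38e-06, n = 16 wells each).

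Pathway effects were compared between experiments. Across genes, which are not independent replicates, the effects of a pathway in a pair of experiments had a Pearson correlation of 0.634 to 0.782 for RA, 0.621 to 0.857 for Wnt, 0.595 to 0.804 for Tgfb, 0.535 to 0.8003 for Bmp and 0.220 to 0.6247 for Fgf. Spearman correlations, which use ranks, were lower. They were 0.352 to 0.534 for RA, 0.473 to 0.698 for Wnt, 0.286 to 0.440 for Tgfb, 0.224 to 0.528 for Bmp and 0.1775 to 0.456 for Fgf. Of 678 genes called for Wnt in both the mesendoderm experiment and the mesendoderm start of the mixed experiment, 650.0 moved the same way (95.9%). For Tgfb all 258 genes called in both the germ layer experiment and the mesendoderm start did. For Bmp, 225 of 229 genes called in both the mesendoderm experiment and the mesendoderm start moved the same way (98.3%), against 117 of 173 for the undirected start (67.6%).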

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

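The tests of an interferon response, of well pairs thinned to equal UMI totals, of Y-linked genes and of genes counted in transfected libraries alone were chosen only after the result was seen.

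Tcfl5, Gm45554 and Cntnap5a had more counts in transfected than in untransfected bulk libraries, and 6 genes had at least 20 counts in a transfected library and at most 3 in each of the 9 other libraries. A hypothesis is that reads of barcodelet RNA were counted at these genes: between the cells with the most and the fewest barcodelet counts, UMIs of Tcfl5 and Cntnap5a stood at a ratio of 0.881 in the germ layer, 0.964 in the mesendoderm and 1.23 in the mixed experiment (95% interval 1.09 to 1.38). Another is an interferon response to the transfected RNA: 6 tested interferon genes had a median log2 change of 0.26 at 24 h (camera adjusted p = 0.886), and none of 14 untested members passed 9 counts in a transfected library. The last is a response shared by both replicate cultures: with counts under 3 set to 3, 2 of the 6 genes lay over 10-fold apart between replicates in the same direction at both times (Tmem63c, 166 and 0 counts at 24 h, 42 and 2 at 72 h; Olfr71, 194 and 9, then 201 and 2), and Ceacam11 (22 and 0, then 22 and 0) and Lct (0 and 27, then 0 and 8) were one-sided too. All ratios of Tcfl5 and Cntnap5a lay under the limit set beforehand for arguing against barcodelet reads. The mixed interval, up to 1.38, reached past it. These ratios cannot decide the question for the bulk libraries. Barcodelet libraries were the short-fragment part of the same cDNA, so barcodelet reads may be few in the transcriptome libraries where the ratios were taken. Gm45554 was not in that test. The 3 explanations cannot be told apart. The mixed interval spans its limit, and the median of the tested interferon genes lies between the limits set for it. The counts of Ceacam11 and Lct are too low to place their ratios.

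The RA effect on Hox genes was lower from the mesendoderm start (16 of 19 tested Hox genes called, all lower, median -2.51), and mesendoderm wells were deeper. With every well thinned to the shallowest, 1 or 2 Hox genes could still be tested and 1 was called, which decides nothing. With each of 70 pairs of wells of the same treatment thinned to the shallower (140.0 wells, median 482102 UMIs), at least 13 Hox genes were called, all lower, and 263 to 288 genes in all. A difference in UMI totals per well is thus excluded as the whole cause, while cell numbers and UMIs per cell were not matched. A biological effect of the start state stays open as a hypothesis, as do other differences between wells of the starts, which were not tested.

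Counts of the Y-linked genes Ddx3y, Uty and Eif2s3y differed within the sorted groups: 0 in Foxa2GFPplus 1, 71 in 3 and 65 in 4. The hypothesis that part of the Foxa2GFPplus libraries holds cells of another origin was drawn from these counts, so they do not test it, and no independent test was run. The sums were 250.0 and 208 in the libraries labelled Tdgf1GFPplus, where Tdgf1 stood below its level in Foxa2GFPminus. They were 0 in untransfected cells, 4 and 4 at 24 h after transfection, and 4 and 0 at 72 h. These sums leave open which libraries hold which cells. A mixture, a wrong label, a second line and loss of the Y chromosome in culture were not tested against one another, and no biological explanation was tested.

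Scores of the 8 control wells of each start were searched for a well that lay apart from the others, relative to their range. From the undirected start, 1 well did in the embryonic fibroblast score (5.60 against at most 4.67). So did 1 in the interferon score (5.04 against at most 3.96) and 1 in the unfolded protein score (5.67 against at most 5.54). From the mesendoderm start, 1 did in the naive pluripotency score (6.99 against at most 6.69) and 1 in the general pluripotency score (7.45 against at most 7.30). Each score was judged on its own, and whether the same well lay apart in more than 1 score was not examined. Chance picks out about 1 in 20 such groups, and 5 of 48 were picked out. The effects of RA, Wnt, Bmp and Fgf differed between the starts for 499, 683, 17 and 129 genes in the test of that difference. Barcodelet counts also appeared under barcodes outside the called cells of the transcriptome matrix. They were 26.2% of 14837680 counts in the germ layer experiment and 9.07% of 26169233 in the mesendoderm experiment.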

How the results depend on the processing

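The crossed numbering, the mesendoderm counts summed per condition and Foxa2GFPplus replicate 1 as the sole library of its group were chosen only after the result was seen. Each total below is a count of called genes, with the value as reported in brackets, and the cause of a change was not tested unless stated. Depth limited the mesendoderm experiment most, with 2328 genes tested against 10614 in the germ layer and 8791 in the mixed experiment.

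Median-of-ratios scaling left all 34 totals within 1.5 times. DESeq2 did so for 30 of 34, the others being Foxa2GFPplus against Foxa2GFPminus 991 (327) and against Tdgf1GFPplus 2179 (1397), Tdgf1GFPplus against Foxa2GFPminus 138 (0), and Shh 2 (1). Without the filter on low counts, which tests more genes, 18 of 37 stayed within 1.5 times. The others were 24 h 14 (4), 72 h 21 (3), 72 h against 24 h 13 (0), Foxa2GFPplus against Foxa2GFPminus 1172 (327) and against Tdgf1GFPplus 2215 (1397), and Tdgf1GFPplus against Foxa2GFPminus 173 (0). In the mesendoderm experiment they were RA 1379 (510), Wnt 2630 (921), Tgfb 532 (235), Bmp 1442 (682), Fgf 397 (216), Notch 11 (27), Shh 8 (1) and interactions 1572 (532). In the mixed experiment they were Tgfb from the undirected start 553 (364), the start-state differences of Tgfb 42 (0), Bmp 93 (17) and Fgf 281 (129), and interactions 1852 (951). With all 13 bulk libraries in 1 fit the totals were 24 h 2 (4), 72 h 0 (3, with 187 genes at an unadjusted edgeR p under 0.05), Foxa2GFPplus against Foxa2GFPminus 1363 (327) and against Tdgf1GFPplus 2879 (1397), and Tdgf1GFPplus against Foxa2GFPminus 79 (0).

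With pairwise products, 24 of 28 totals stayed within 1.5 times, except germ layer Tgfb 1132 (745) and Fgf 1331 (842), Shh 2 (1) and the RA start-state difference 213 (499). With at least 20 cells per population, 9 of 16 did, except undirected Wnt 1756 (3176), Bmp 340.0 (687) and Fgf 712 (1166), the start state 1278 (2254), and the start-state differences of RA 761 (499), Wnt 322 (683) and Tgfb 3 (0). That minimum left 3 mesendoderm wells and could not give mixed interactions, and it removed no germ layer population. Leaving out the 5% of cells with the most UMIs moved the start-state differences of Bmp, to 8 (17), and Fgf, to 45 (129). A minimum of 2000 UMIs removed no cell. Summed per condition, Wnt had 1523 (921) and Shh 2 (1). With an estimated correlation, called lists fell to 0 (53) in bulk, 14 (45) in the germ layer, 14 (25) in the mesendoderm and 57 (129) in the mixed experiment. Pseudocounts of 1 and 20 gave 27 and 28 called list scores (28) in the germ layer, 31 and 37 (32) in the mesendoderm and 77 and 75 (75) in the mixed experiment.

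With a replicate left out, which tests fewer samples, totals ranged from 3 to 8 at 24 h, 2 to 43 at 72 h and 0 to 16 between the times, 44 to 2909 for Foxa2GFPplus against Foxa2GFPminus, 230.0 to 4134 against Tdgf1GFPplus, and 0 to 0 for Tdgf1GFPplus against Foxa2GFPminus. Where a group of 2 libraries lost 1, the lone sample is assumed to vary like the other groups. Foxa2GFPplus replicate 1 as sole library gave 444 against Foxa2GFPminus. In the mesendoderm experiment the ranges were 333 to 447 for RA, 726 to 860.0 for Wnt, 115 to 230.0 for Tgfb, 482 to 582 for Bmp, 88 to 182 for Fgf, 9 to 25 for Notch and 0 to 2 for Shh. Tgfb plus had fewer wells than Tgfb minus there, so leaving out a replicate, or a replicate block, need not weigh both levels alike. In undirected wells they were 1338 to 2110 for RA, 1748 to 2145 for Wnt, 123 to 157 for Tgfb, 166 to 195 for Bmp and 346 to 471 for Fgf. In mesendoderm-start wells they were 988 to 2065 for RA, 1803 to 3010 for Wnt, 142 to 324 for Tgfb, 171 to 537 for Bmp and 450.0 to 541 for Fgf. The start state had 1089 to 1397, and the start-state differences 57 to 145 for RA, 72 to 240.0 for Wnt, 0 to 0 for Tgfb, 0 to 0 for Bmp and 8 to 9 for Fgf. Of 2877 values of named genes over these alternatives, 2684 kept direction and call, 172 lost the call and 13 gained it. The 8 that turned had no call, and the ranges of these log2 changes over left-out replicates were -0.237 to 0.0103 for Foxa2 and -0.291 to 0.0711 for Tdgf1 at 24 h (above 0 without 24 h replicate 2 and without untransfected replicate 1). At 72 h they were -0.245 to 0.137 for Tdgf1 (also 0.105 without 72 h replicate 1) and -0.354 to 0.00917 for Dusp6 (both above 0 without untransfected replicate 1), and between the times -0.130 to 0.222 for Tdgf1 (below 0 without 72 h replicate 2). For Tdgf1GFPplus against Foxa2GFPminus they were -1.25 to 1.71 for Foxa2 and -0.101 to 1.36 for Tcfl5 (both below 0 without Tdgf1GFPplus replicate 1).

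The replicate numbers were not found to pair the bulk libraries: deviations of same-numbered libraries correlated at 0.124 (24 h and 72 h), -0.248 (24 h and untransfected), -0.118 (72 h and untransfected), -0.0977 (Tdgf1GFPplus and Foxa2GFPminus), 0.180 (Foxa2GFPplus 1 and Tdgf1GFPplus 1) and 0.0666 (Foxa2GFPplus 1 and Foxa2GFPminus 1) over 7727 genes. With the replicate number as a block the totals were 5 at 24 h, 3 at 72 h, 0 between the times and 254 (0) for Tdgf1GFPplus against Foxa2GFPminus. In the mesendoderm experiment they were RA 537, Wnt 988, Tgfb 183, Bmp 716, Fgf 200.0, Notch 26 and Shh 2 (1). In undirected wells they were 3072, 3202, 396, 742 and 1206 for RA, Wnt, Tgfb, Bmp and Fgf, and in mesendoderm-start wells 2725, 3684, 651, 1001 and 1269. The start state had 1560 and the start-state differences 529, 719, 0, 18 and 151 in the same order. With the untransfected numbers crossed, the block gave 8 genes at 24 h and 5 at 72 h. No paired analysis was possible because Foxa2GFPplus shared 1 number with each other sorted group, which leaves a single pair, and because the germ layer experiment had 1 population per condition. This holds for the comparisons of Foxa2GFPplus and of the germ layer experiment alone.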

Other observations

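The tests of cell numbers per population were chosen only after the result was seen.

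Interferon response genes fell with Wnt in mesendoderm-start wells and in the germ layer experiment. In mesendoderm-start wells of the mixed experiment 9 of 10 did (9 adjusted over the list alone), with Ifitm3 down by 0.66 ± 0.08 and the chemokine Cxcl10 at 0.499 ± 0.863 against 8.98 ± 19.4 CPM (camera adjusted p = 6.6e-05, and adjusted p = 0.0527 with an estimated correlation). In the germ layer experiment 5 of 11 fell (7 adjusted over the list alone), with Cxcl10 at 2.20 ± 1.82 against 16.9 ± 16.46 CPM (camera adjusted p = 0.000877, and adjusted p = 0.253 with an estimated correlation). In undirected wells 4 of 10 fell (4 adjusted over the list alone), and the list itself did not pass (camera adjusted p = 0.0825, and adjusted p = 0.491 with an estimated correlation). Naive pluripotency genes in mesendoderm-start wells moved in opposite directions with Fgf and Tgfb. With Fgf, 11 of 14 fell and 1 rose (11 and 1 adjusted over the list alone), with Nanog down by 0.65 ± 0.11 (camera adjusted p = 3.39e-09, and adjusted p = 0.0034 with an estimated correlation). With Tgfb, 7 of 14 rose (8 adjusted over the list alone), with Dppa5a up by 1.11 ± 0.08 and Nanog by 0.92 ± 0.11 (camera adjusted p = 5.49e-12, and adjusted p = 0.000476 with an estimated correlation).

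Some genes of cholesterol synthesis and of glycolysis moved in the germ layer experiment, and none of the list results that follow passed with an estimated correlation. Of 16 cholesterol synthesis genes 11 rose with Bmp (11 adjusted over the list alone, camera adjusted p = 0.000183, and adjusted p = 0.141 with an estimated correlation), and 8 fell with Wnt (9 adjusted over the list alone, camera adjusted p = 0.00281, and adjusted p = 0.304 with an estimated correlation). Of 15 glycolysis and hypoxia genes 7 fell with Bmp (7 adjusted over the list alone), with Eno1 down by 0.41 ± 0.04 (camera adjusted p = 0.00708, and adjusted p = 0.131 with an estimated correlation). The number of cells assigned to a population differed between levels for RA, Wnt and Fgf in some experiments, and did not pass the test for Tgfb, Bmp, Notch or Shh in any (lowest adjusted permutation p = 0.101). Nor did it pass for RA in the mesendoderm experiment (ratio of plus to minus 0.960, adjusted permutation p = 0.607), Wnt in the germ layer (1.01, 0.937) and mesendoderm experiments (1.005, 0.937) and in mesendoderm-start wells (0.9375, 0.718), RA in undirected (1.17, 0.484) and mesendoderm-start wells (1.27, 0.118), and Fgf in the germ layer experiment (1.28, 0.101) and undirected wells (1.252, 0.264). Cell numbers were 163 ± 38.6 with RA plus and 109 ± 27.9 with RA minus in the germ layer experiment (n = 16 each, adjusted permutation p = 0.000587), and 8.71 ± 3.57 against 6.39 ± 3.73 for Fgf in the mesendoderm experiment (n = 192 each, adjusted permutation p = 0.00011). In the mixed experiment it was 14.4 ± 6.91 with Wnt plus against 30.25 ± 13.2 with Wnt minus in undirected wells (n = 32 each, adjusted permutation p = 0.00011). For Fgf in mesendoderm-start wells it was 50.2 ± 21.0 against 34.2 ± 14.4 (n = 32 each, adjusted permutation p = 0.00346). The unadjusted p of 1e-05 behind both values of 0.00011 is the smallest that 100000 resamples can give.

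Other assignments of the pathway levels to the same populations were fitted. Each moved the whole set of levels of a population, so all pathways of an experiment were broken at once. Effects of the other pathways then fell into the residual spread. The counts set the real design as a whole against shuffled ones. They do not exclude chance for 1 pathway with the others kept in place. In the germ layer experiment 1 of 100 assignments, the real one, gave as many genes for each pathway: RA 2937 (highest other 247), Wnt 2542 (36), Tgfb 745 (512), Bmp 4575 (210) and Fgf 842 (4). So it was for the interactions there, 1621 (99, 1 of 25 assignments). In the mesendoderm experiment 1 of 100 assignments gave as many genes for RA 510 (2), Wnt 921 (2), Tgfb 235 (3), Bmp 682 (2), Fgf 216 (2) and Notch 27 (2). For Shh 8 of 100 gave at least the real count of 1 (highest other 8), so chance stays open there by this count too. In the mixed experiment 1 of 36 assignments gave as many genes for undirected RA 3019 (1), Wnt 3176 (3), Tgfb 364 (22), Bmp 687 (2) and Fgf 1166 (4). So did 1 of 36 for mesendoderm-start RA 2634 (105), Wnt 3612 (1), Tgfb 612 (0), Bmp 942 (1) and Fgf 1192 (1). The same holds for the start state, 2254 (2), and the start-state differences of RA 499 (1), Wnt 683 (1), Bmp 17 (0) and Fgf 129 (12). For the start-state difference of Tgfb all 36 assignments gave at least the real count of 0, by edgeR (450 at an unadjusted p under 0.05, DESeq2 0), which a real count of 0 fixes in advance, so this decides nothing about chance. The source of the highest other there, 154, was not traced, nor was that of the 512 for germ layer Tgfb. The assignments were too few for a share under 0.05 for the interactions of the mesendoderm (532, highest other 9, 16 assignments) and mixed experiments (951, highest other 10, 8 assignments).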
